A study of Mus musculus with 24 samples.

How the data were processed

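RNA from splenic B cell subsets of female NOD and B6 mice aged 7 weeks was measured on Affymetrix mouse genome arrays. Per the labels, T cells and myeloid cells were depleted through CD3 and CD11b, and the subsets were sorted on IgM, CD21/35, CD24, B220, CD93 and CD23. RNA was labelled in a two-step amplification primed from the poly(A) tail. The genes encoding the sort markers (Ighm, Cr2, Cd24a, Ptprc, Cd93, Fcer2a) are read as a check on the sort and not as findings. Cells of 1 strain and 1 experiment came from 1 pool of mice, and the experiment was repeated, which gave 4 pools and 24 arrays.

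The deposited values are log2 values that the authors made with RMA, per the submitters' processing notes. The RMA version is not given in the sources used here, and neither is the base of the logarithm, which was taken as 2. The largest range of a probe set over the arrays was 9.02. Each probe set of the deposited table was found centred on its own median over the 24 arrays, the largest median being 5e-07 in size, so no expression level and no signal over background could be had. Of 45101 probe sets, 64 were controls, 34945 had 1 gene, 932 had several genes and 9160 had none in the platform's annotation, which paired probe sets with gene symbols. Of those with 1 gene, 34741 were matched by gene number to the NCBI gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed.

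Choices made before the data were examined are kept except where centring made them impossible. The planned filter on dim genes and the planned choice of the brightest probe set need expression levels. Applied literally the filter kept all 18193 genes. In its place no filter was used, and each gene was represented by the probe set with the largest standard deviation over the 24 arrays. This choice was made after the values were seen and used no group labels. It still favours probe sets that differ between strains or subsets, so differences may be larger than in other probe sets of a gene. No filter as an alternative (now the same as the analysis itself), a stricter filter on dim genes and cyclic loess scaling were not run.

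Differences were tested with limma 3.58.1 in R 4.3.3. For comparisons of groups 1 mean per group was fitted over the 12 groups, so that all 24 arrays shared 1 estimate of the spread, followed by contrasts and eBayes. For NOD against B6 over subsets the 6 subsets of each pool were averaged first, and limma was run on 4 pool means. Benjamini-Hochberg adjusted p under 0.05 counted as called. Every p-value rests on 2 arrays per group or 2 pools per strain. Arrays of 1 pool are not independent, and with a random block the correlation within a pool was 0.116. Errors beside differences are standard errors from limma, and those beside group values are standard deviations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

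Whether replicate numbers pair arrays by pool was checked by correlating the deviations of arrays from their group means. Same-numbered B6 arrays of T1, T2FO, T3 and T2MZ had correlations of 0.77 to 0.89, and FO with MZ 0.74. FO and MZ against the other 4 had -0.66 to -0.39, so their numbers may be crossed relative to the others. The 5' control signal divides the arrays in the same way. It was higher in replicate 1 of those 4 subsets and in replicate 2 of FO and MZ. The check therefore cannot tell crossed numbers from a difference in 5' signal. In NOD the correlations ran from -0.059 to 0.51. Numbers pair arrays only within a strain, so blocks on the number are given in the report for comparisons within strains and for interactions. Between strains the block pairs unrelated pools, and its value is listed with the alternatives only.

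Lists of genes were written before the data were examined. The 19 lists were gate markers, marginal zone, follicular, immature B cell, Notch pathway, B cell receptor signalling, BAFF with NF-kB and survival, migration and adhesion, cell cycle, interferon response, Toll-like receptors, MHC class II and costimulation, plasma cell and secretion, immediate early and stress, T cell, myeloid cell, dendritic cell, NK cell, and erythroid and platelet. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The signature of B6 took up to 100 genes each way from MZ against FO of B6 and was read only in subsets whose arrays did not enter it.

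Genes were named by a rule. For NOD against B6 in FO, T2MZ, MZ and over subsets and for MZ against FO the 8 largest called differences each way with no overlap between the arrays of the arms were named, and 4 each way elsewhere. From each list up to 4 called members with the smallest adjusted p were taken, or up to 2 with the smallest p where none was called. Gate markers and Nnt were added in comparisons between strains. Genes with several names for 1 probe set and immunoglobulin variable genes were not named. A further gene that the rule names is not reported here. Groups of 2 against 2 arrays do not overlap by chance in 2 of 6 orders, so the condition says little in single subsets.

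The script was tested on simulated data with the arrays' own spread and 200 of 18193 genes changed. For NOD against B6 in MZ it recovered 40% of changes of log2 1 and 77% of log2 2, for MZ against FO in B6 33% and 78%, and for NOD against B6 over subsets 49.5% and 90%. False calls were 1.98% to 8.05% of calls and no call had the wrong sign. Each simulated array varied on its own, without the correlation within pools or the classes of 5' control signal of the real arrays. The rates therefore need not hold for the real comparisons.

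Alternatives were the mean of all probe sets of a gene, eBayes with trend and robust, a replicate block, the pool as a random block, only the arrays of the groups compared, and leaving out each array in turn. Added after the data were seen were the difference between 5' and 3' control signal as a covariate, only genes with a standard deviation above the median, arrays centred on their medians, the class of 5' control signal as a block, crossed numbers as a block, 1 strain's contrast alone, and the FO and MZ numbers of B6 crossed between the pools. Probe sets without a single gene name were not used here except for a count. No comparison was made under other labels for the NOD arrays.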

Results

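Gene expression was measured in 6 B cell subsets sorted from the spleens of female mice of 2 inbred strains at 7 weeks of age. NOD mice develop autoimmune diabetes spontaneously, and C57BL/6 (B6) mice, which do not, served as the comparison strain. The labels name the subsets T1, T2FO, T3, FO, T2MZ and MZ, that is the transitional stages, the mature follicular and marginal zone cells, and the transitional cells on the way to each of them. Each subset of each strain was measured on 2 arrays, which gave 24 arrays in 12 groups. Cells of 1 strain and 1 experiment came from a single pool of mice, so the arrays trace back to 4 pools, 2 per strain. The deposited values are log values of 45101 probe sets, each centred on its own median over the 24 arrays, so they show differences between arrays but no expression level. The log base is not given in the sources used here and was taken as 2. Array medians lay between -0.039 and 0.059, no pair of arrays was identical, and the highest correlation between any pair was 0.89. The spread between replicates was 0.514 in B6 and 0.28 in NOD on the log2 scale (root mean square over 18193 genes). Only 2 arrays per group limit the precision of every value below.

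Transcripts of the surface proteins used to sort the cells were examined first, as a check on the labels. Ighm could not serve, since it was higher in replicate 2 of every group, with -2.05 and 2.91 in the NOD arrays labelled T1. Cd24a (0.40 ± 0.04 in B6 T1, -0.11 ± 0.86 in B6 MZ) and Ptprc (-1.08 ± 0.42 and -0.15 ± 0.49) set these subsets less clearly apart. The check therefore rests on the remaining gate transcripts, Cr2, Cd93 and Fcer2a. In B6, Cr2, which encodes CD21 and CD35, rose from -1.72 ± 0.15 (SD, n = 2) in T1 to 0.86 ± 0.52 in MZ. Cd93, a marker of immature B cells, was 3.06 ± 0.11 in B6 T1, 2.75 ± 0.03 in T2FO, 2.52 ± 0.43 in T3 and -0.80 ± 0.05 in MZ. The NOD arrays followed another order. Those labelled T1 had the highest Cr2 value of the NOD groups, 1.20 ± 0.06, and the lowest Cd93 value, -2.09 ± 0.07. The NOD arrays labelled T2FO had the lowest Cr2, -1.29 ± 0.14, with Cd93 at 0.21 ± 0.43. Fcer2a, which encodes CD23, was low in B6 T1 (-1.23 ± 0.09) and B6 MZ (-1.53 ± 0.45), and in NOD it was lowest in the arrays labelled T1 (-1.56 ± 0.11) while those labelled MZ reached 0.97 ± 0.07. A pair of marginal zone genes, chosen after their values were seen, went with these gate transcripts. S1pr3, a sphingosine phosphate receptor, stood at 2.88 ± 0.12 in B6 MZ and at 3.72 ± 0.07 in the NOD arrays labelled T1, against 1.88 ± 0.55 in those labelled MZ. Tlr3 was 3.72 ± 0.07 in B6 MZ, 4.75 ± 0.11 in the NOD arrays labelled T1 and 1.91 ± 0.33 in those labelled MZ. The NOD groups are therefore called arrays labelled T1, T2FO and so on, and every direction that depends on a NOD subset label carries this limit.

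**Figure D1:**
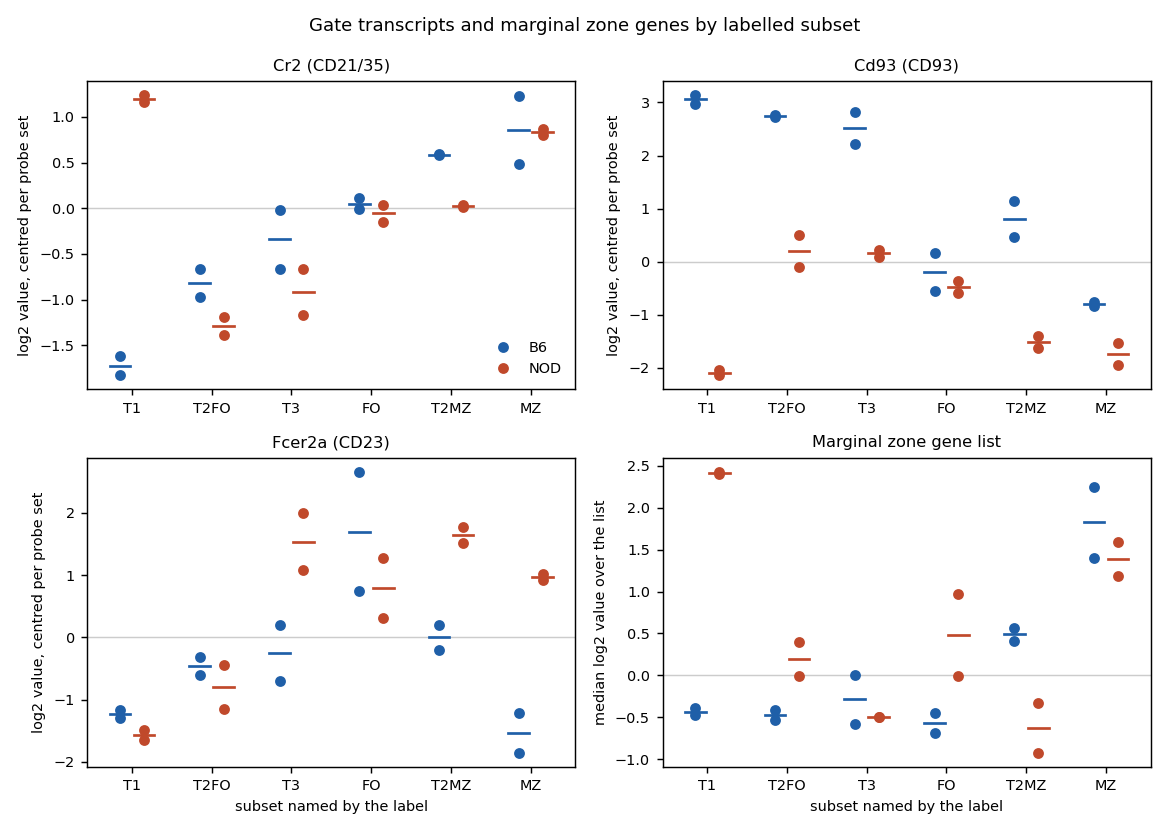
Values of Cr2, Cd93 and Fcer2a and the median of the marginal zone list (vertical axes, log2, each probe set centred on its median) by labelled subset (horizontal axis). Points are arrays, short lines are means of 2 arrays, B6 is blue and NOD is red. The NOD arrays labelled T1 have the highest Cr2 of the NOD groups, 1.20 on average, and the B6 T1 arrays the lowest of B6, -1.72.

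The strain labels were checked with Nnt, a mitochondrial gene that carries a deletion in C57BL/6J. Nnt was 0.99 ± 0.14 (SE) log2 units higher in NOD over the subsets (limma with Benjamini-Hochberg adjustment, adjusted p = 0.038). In single subsets the difference ran from 0.65 ± 0.42 to 1.25 ± 0.42 and passed the threshold in none of them. Replicate 2 of B6 FO (0.30) and of B6 MZ (0.03) lay within the range of the NOD arrays (-0.11 to 0.52), and the other 10 B6 arrays lay below it. These 2 are also the B6 arrays whose 5' control signal was like that of NOD. The check therefore does not separate strain from that signal in them.

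The signal of the control probe sets differed between the strains, and its cause was not tested. The control probe set at the 5' end of the beta-actin transcript lay between -0.538 and 0.795 in the 12 NOD arrays. In 6 B6 arrays it lay between -4.04 and -3.27, in 4 between -1.36 and -0.77, and in the remaining 2, replicate 2 of FO and of MZ, between 0.42 and 0.474. At the 3' end of the same transcript all 24 arrays lay between -0.373 and 0.214. The Gapdh control did not show a fall at the 5' end alone. Its 3' probe set lay between -1.58 and -0.468 in the 6 B6 arrays lowest in beta-actin, and between -0.0547 and 0.466 in NOD. In B6 FO replicate 1 its 5' value (-1.64) and its 3' value (-1.58) were alike. The strain comparisons in T1, T2FO, T3 and T2MZ therefore set B6 arrays with lower 5' signal against NOD arrays, and in FO and MZ 1 of the 2 B6 arrays was like NOD.

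**Figure D2:**
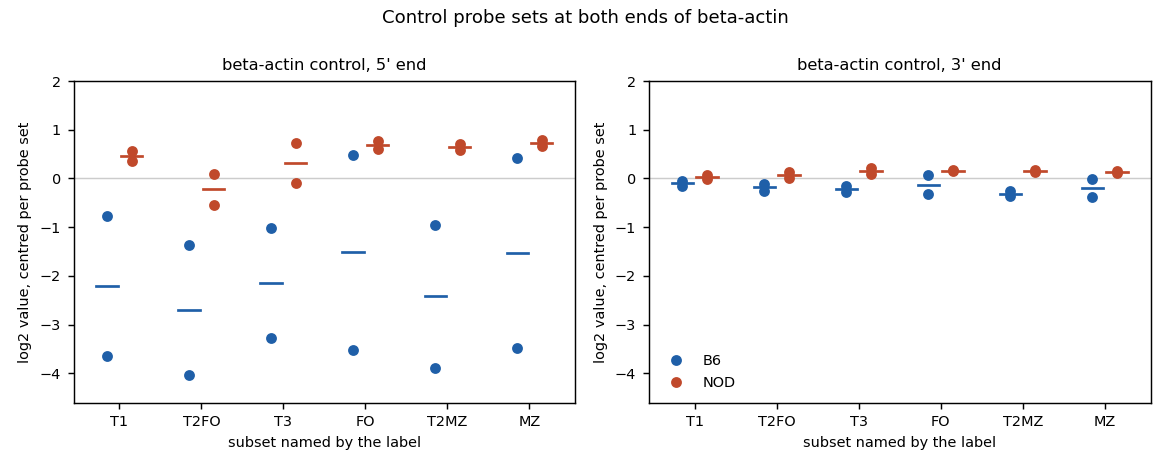
Control probe sets at the 5' end (left) and the 3' end (right) of beta-actin, as log2 values centred per probe set (vertical axes), by labelled subset (horizontal axis). Points are arrays, short lines are means of 2 arrays, B6 is blue and NOD is red. At the 5' end 6 B6 arrays lie between -4.04 and -3.27, while the NOD arrays lie between -0.538 and 0.795.

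The series asks how gene expression differs between NOD and B6 B cells. Averaged over the 6 subsets, the comparison does not depend on which NOD array carries which subset label. NOD cells gave a far higher signal for Ctse, the aspartic protease cathepsin E (5.48 ± 0.12 log2 units, SE, 2 pools per strain). The fatty acid desaturase gene Scd2 was also higher (4.72 ± 0.13). Signal was far lower in NOD for the tripartite motif genes Trim12a (-6.52 ± 0.14) and Trim12c (-5.90 ± 0.20) and for Ifi213 (-5.36 ± 0.20), a member of an interferon-inducible family. The arrays were designed on the B6 sequence, so for every gene called lower in NOD here and below a lower value is a lower signal and need not be less transcript. Values in both directions are those of a gene's most variable probe set, and its other probe sets often differed less. With further probe sets, 332 of 432 genes called higher had others that differed by under 25% as much or the other way. Among genes called lower 232 of 328 did, so increases need not be more transcript either. The class II MHC gene H2-Aa was lower in its most variable probe set (-3.14 ± 0.10), but with the mean of its probe sets the difference was -0.28 and not called, and it lay between -0.60 and 0.06 in single subsets. Pik3ap1, an adaptor that links the B cell receptor to phosphoinositide kinase, was higher by 2.50 ± 0.12 log2 units. Of 18193 genes, 944 passed the threshold of 0.05 (limma on pool means, Benjamini-Hochberg adjustment), 515 higher and 429 lower in NOD. Among the largest increases were also BC018473 (5.25 ± 0.16), Zfp979 (4.84 ± 0.26), Mtrex (4.58 ± 0.54), the phosphatase gene Inpp5f (3.97 ± 0.18), AI506816 (3.82 ± 0.14) and the cell cycle inhibitor Cdkn1b (3.46 ± 0.30). The largest decreases also took in the ribosomal protein gene Rps9 (-5.30 ± 0.14), the peptide transporter Slc15a2 (-5.04 ± 0.14), the serine synthesis enzyme Phgdh (-4.70 ± 0.29) and Mir1931 (-4.63 ± 0.13). Genes named here by the size of their difference were chosen so that all 12 NOD arrays lay on one side of all 12 B6 arrays. Of the 944 called genes 462 met that condition, and of all 18193 genes 606 did. The named genes had adjusted p between 0.00345 and 0.0273 (limma with Benjamini-Hochberg adjustment).

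**Figure D3:**
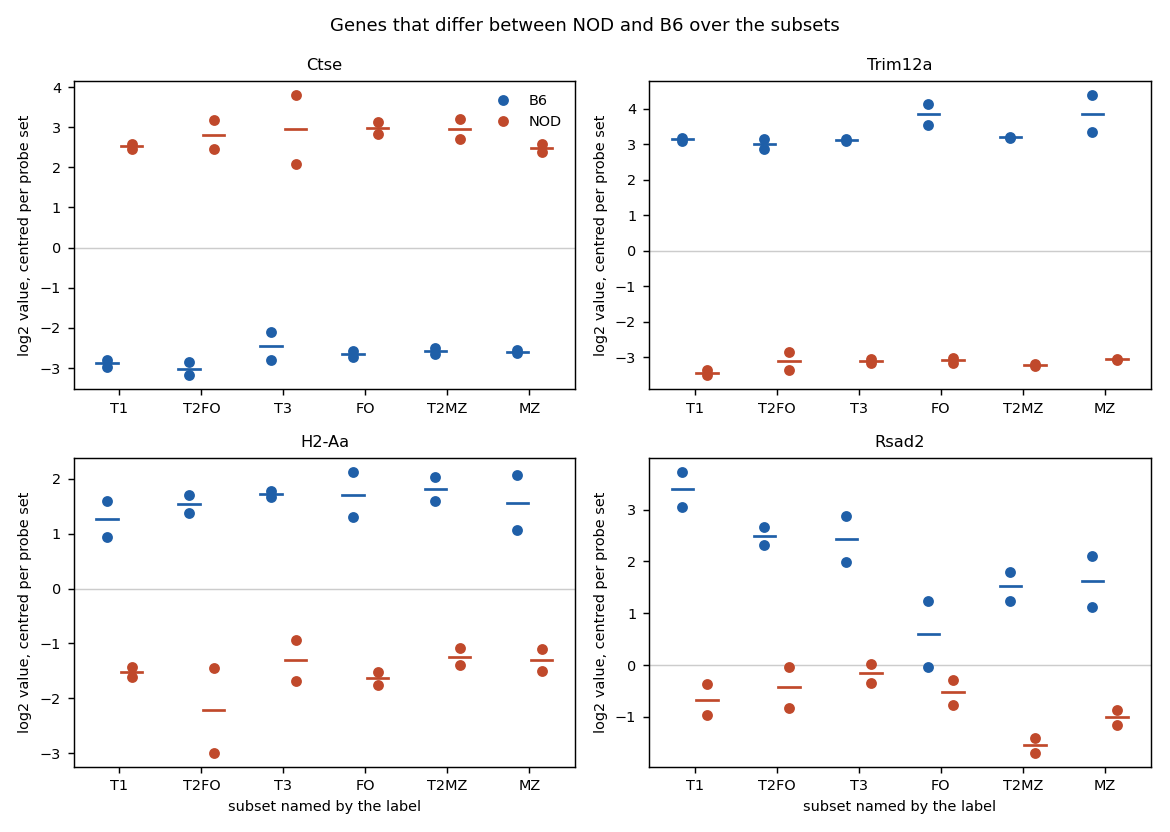
Ctse, Trim12a, H2-Aa and Rsad2 as log2 values centred per probe set (vertical axes) by labelled subset (horizontal axis). Points are arrays, short lines are means of 2 arrays, B6 is blue and NOD is red. Ctse averages 5.48 log2 units higher in NOD over the subsets, and the difference in Trim12a is -6.52. H2-Aa is shown for its most variable probe set only.

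Of 16 measured interferon response genes, 3 fell in NOD over the subsets, namely the antiviral gene Rsad2 (-2.73 ± 0.13), the RNA sensor Ifih1 (-1.71 ± 0.17) and Rtp4 (-2.04 ± 0.26), and Stat2, which transmits the interferon signal, rose (1.10 ± 0.16). Adjusted over the list alone, 11 were lower and 1 was higher. The list median was -1.11 (limma's camera, adjusted p = 1.06e-05), with adjusted p = 0.673 when the correlation between genes was estimated. Of 21 B cell receptor signalling genes, Pik3ap1 and the inhibitory receptor Cd22 (1.86 ± 0.25) rose and none fell (7 rose adjusted over the list alone), with a list median of 0.55 (camera adjusted p = 0.00221, and adjusted p = 0.673 with an estimated correlation). In the list of 13 class II MHC and costimulation genes, H2-DMb2 (1.74 ± 0.17) and the class II transactivator Ciita (1.88 ± 0.22) rose, H2-Aa and Cd86 (-0.78 ± 0.12) fell (6 and 2 adjusted over the list alone), and the list median was 0.49 (camera adjusted p = 0.0456, 0.673 with an estimated correlation). The marginal zone list (median 0.40), the migration list (0.36), the plasma cell list (0.56) and the immature B cell list (-0.27) also passed camera's threshold, and each had an adjusted p of 0.673 with an estimated correlation. Single members that passed were the NF-kB kinase Ikbkb (1.49 ± 0.15), the chemokine receptor Ccr6 (0.97 ± 0.10), the integrin gene Itgal (-0.78 ± 0.11), Dock2 (-2.26 ± 0.36), Tlr6 (1.21 ± 0.13), the receptor kinase Irak1 (1.05 ± 0.17), the transcription factor Sox4 (-1.83 ± 0.14) and the heat shock gene Hspa1b (-1.17 ± 0.16). Among the gate transcripts Cd93 was lower (-2.26 ± 0.10) and Ptprc higher (1.01 ± 0.13). The follicular, Notch, BAFF, cell cycle, Toll-like receptor, immediate early, T cell, myeloid, dendritic, NK and erythroid lists did not pass, with medians between -0.41 and 0.36.

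The number of genes called over the subsets rested on the pools and on the probe sets. It was 7 without NOD pool 1 and 0 without NOD pool 2 (limma, with 2574 genes at an unadjusted p under 0.05), 2401 without B6 pool 1 and 1643 without B6 pool 2. It was 49 when the FO and MZ numbers of B6 were crossed between the pools, which puts the 6 B6 arrays with the lowest 5' signal into 1 pool. The balance of directions was not stable either, since on the 24 arrays taken as independent 2106 genes were higher and 1856 lower, and with the 5' minus 3' control difference as a covariate as well 2329 and 3031. The choice of probe set mattered too, as the mean of all probe sets of a gene gave 433 genes, 214 higher and 219 lower.

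Within the arrays labelled T1, NOD was higher in genes that also mark mature marginal zone cells. Asb2, a Notch target (5.05 ± 0.31, SE, n = 2 and 2), Tlr3 (5.48 ± 0.41), Dtx1, a regulator of Notch signalling (3.52 ± 0.36), and the antigen-presenting molecule Cd1d1 (2.52 ± 0.27) were higher in NOD. Of 9 marginal zone genes 7 rose (8 adjusted over the list alone) and none fell, with a list median of 3.52 (limma's camera, adjusted p = 2.02e-12, and 0.0175 with an estimated correlation). Of 10 immature B cell genes 5 fell (6 adjusted over the list alone), among them Sox4 (-5.45 ± 0.45), Spn (-2.39 ± 0.47), Lef1 (-1.26 ± 0.24) and the recombinase gene Rag1 (-0.99 ± 0.18), with a median of -1.12 (camera adjusted p = 9.25e-07, and 0.00263 estimated). These are the arrays whose gate transcripts run against the label, with Cr2 higher by 2.92 ± 0.25 and Cd93 lower (-5.15 ± 0.28). In all, 1435 genes passed the threshold, 830 higher and 605 lower. With the 5' minus 3' control difference as a covariate the balance turned, with 2007 higher and 2212 lower. With only the arrays compared 395 passed. Class II MHC genes (median 0.93) and B cell receptor genes (0.34) had camera adjusted p of 0.019 and 0.025, and adjusted p = 0.408 and 0.534 with an estimated correlation. The 4 largest increases were Scd2 (6.39 ± 0.30), Mtrex (5.92 ± 1.27), BC018473 (5.90 ± 0.27) and Zfp979 (5.82 ± 0.40), and the largest decreases were Trim12a (-6.57 ± 0.27), Trim12c (-6.37 ± 0.37), Slc15a2 (-5.67 ± 0.27) and Sox4. Of 16 interferon response genes 8 fell (12 adjusted over the list alone), led by Rsad2 (-4.05 ± 0.46) and Oas2 (-2.57 ± 0.42), while Stat2 rose (1.73 ± 0.26), and the list median of -1.87 had a camera adjusted p of 2.15e-07 and an adjusted p of 0.167 with an estimated correlation. Of 16 Toll-like receptor genes 4 rose (8 adjusted over the list alone), including Tlr3, Tlr6 (1.30 ± 0.21) and Ly96 (1.51 ± 0.37), and the adaptor Tirap fell (-1.04 ± 0.28), with a median of 0.56 and an adjusted p of 0.000625 (0.0227 estimated). The heat shock genes Hspa1a (-3.92 ± 0.97) and Hspa1b (-3.75 ± 1.01) and the immediate early gene Egr1 (-2.96 ± 0.77) fell, but the immediate early and stress list did not pass (camera adjusted p = 0.0933), and its median was -3.04 in NOD replicate 2 against 0.29 in NOD replicate 1. The migration receptors Ccr6 (2.82 ± 0.41), S1pr3 (3.93 ± 0.61) and Gpr183 (1.76 ± 0.38) rose. The count was 792 without B6 T1 replicate 1, 685 without NOD T1 replicate 1 and 854 without NOD T1 replicate 2.

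In the arrays labelled T2FO, several plasma cell genes were higher in NOD. Tnfrsf17, the BCMA receptor of plasma cells (2.24 ± 0.30), the transcription factors Prdm1 (2.71 ± 0.50) and Xbp1 (2.06 ± 0.38) and the endoplasmic reticulum gene Creld2 (1.62 ± 0.22) were higher in NOD. Of 12 plasma cell and secretion genes 6 rose (7 adjusted over the list alone) and none fell, with a list median of 1.71 (camera adjusted p = 1.39e-09, and 0.0409 with an estimated correlation). The list also passed in the arrays labelled FO (median 0.45, camera adjusted p = 0.00465, and 0.504 estimated). In T2FO the marginal zone list (median 0.74, camera adjusted p = 0.00988, and 0.568 estimated) and the B cell receptor list (0.58, camera adjusted p = 0.0338, and 0.751 estimated) passed too. The interferon response list had a median of -1.11 with Rsad2 lower (-2.92 ± 0.46), a camera adjusted p of 2.39e-05 and an adjusted p of 0.568 with an estimated correlation. Across all genes 728 passed, 367 higher and 361 lower, but 175 higher and 210 lower with the mean of all probe sets, 1024 and 1555 with the 5' minus 3' control difference as a covariate, and 14 genes with only the 4 arrays compared. Ctse (5.84 ± 0.41), Mtrex (5.23 ± 1.27), BC018473 (5.05 ± 0.27) and Zfp979 (4.96 ± 0.40) rose most, and Trim12c (-6.12 ± 0.37), Trim12a (-6.09 ± 0.27), Rps9 (-5.50 ± 0.38) and D17H6S56E-5 (-5.45 ± 0.57) fell most. H2-Aa (-3.75 ± 0.46), Cd93 (-2.54 ± 0.28) and Itgal (-0.94 ± 0.24) were lower, and Mzb1 (1.56 ± 0.35), Pik3ap1 (2.21 ± 0.20) and Tlr6 (1.06 ± 0.21) higher. None of 6 NK cell genes was positive (median -0.70, camera adjusted p = 0.0338, and 0.568 with an estimated correlation), and B6 T2FO replicate 2 stood apart with an NK cell list median of 1.46 against -0.08 in replicate 1. The count was 382 without B6 T2FO replicate 1 (169 higher and 213 lower), 337 without B6 T2FO replicate 2 and 291 without NOD T2FO replicate 2.

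In the arrays labelled T3, of 551 genes that passed 420 were also called with the same sign over the subsets, where these arrays take part. Ctse (5.40 ± 0.41), BC018473 (4.67 ± 0.27), Zfp979 (4.34 ± 0.40) and the ubiquitin ligase Nedd4 (4.13 ± 0.61) rose most, and Trim12a (-6.21 ± 0.27), Trim12c (-5.89 ± 0.37), Slc15a2 (-5.44 ± 0.27) and Ifi213 (-5.41 ± 0.37) fell most. Of the 551, 329 were higher and 222 lower in NOD. With only the arrays compared 9 genes passed, 3 higher and 6 lower. Of 21 B cell receptor signalling genes Pik3ap1 (2.46 ± 0.20) and Cd22 (1.91 ± 0.44) rose, with a list median of 0.64 (camera adjusted p = 0.00104, and 0.442 with an estimated correlation). None of 20 cell cycle genes passed alone, although the list median was -0.94 (camera adjusted p = 5.95e-05, and 0.522 with an estimated correlation). B6 T3 replicate 2 stood apart, with a list median of 2.04 against 0 in B6 replicate 1 and -0.36 and -0.05 in NOD. Ikbkb (1.39 ± 0.28), Stat2 (1.07 ± 0.26) and Tlr6 (1.88 ± 0.21) were higher, and Rsad2 (-2.59 ± 0.46), H2-Aa (-3.03 ± 0.46), Notch1 (-0.70 ± 0.15), Itgal (-1.20 ± 0.24) and Cd93 (-2.36 ± 0.28) lower. Without B6 T3 replicate 1 the balance turned, with 128 higher and 280 lower. The count was 174 without NOD T3 replicate 1 and 324 without NOD T3 replicate 2.

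In the arrays labelled FO, several macrophage transcripts and some of dividing cells were higher in NOD. The complement genes C1qc (3.44 ± 0.52), C1qa (2.89 ± 0.54) and C1qb (3.80 ± 0.80), the lysosomal gene Cd68 (2.68 ± 0.47) and the mannose receptor Mrc1 (3.86 ± 0.67) were higher in NOD. Of 12 myeloid genes 5 rose (7 adjusted over the list alone) and none fell, with a list median of 1.80 (camera adjusted p = 6.42e-05, and 0.504 with an estimated correlation). The proliferation genes Mki67 (3.43 ± 0.86) and Cdk1 (2.77 ± 0.61) rose, all 20 cell cycle genes were positive, and the list median was 1.31 (camera adjusted p = 9.70e-07, and 0.504 estimated). In all 718 genes passed, 417 higher and 301 lower, but 21 with only the arrays compared, 10 higher and 11 lower. Beside Ctse (5.63 ± 0.41), BC018473 (5.28 ± 0.27), Zfp979 (4.78 ± 0.40) and Scd2 (4.62 ± 0.30), the largest increases were Inpp5f (4.20 ± 0.32), Nedd4 (4.03 ± 0.61) and AI506816 (3.84 ± 0.29). The largest decreases included Trim12a (-6.93 ± 0.27), Ifi213 (-5.87 ± 0.37), Rps9 (-5.85 ± 0.38), Trim12c (-5.67 ± 0.37), D17H6S56E-5 (-5.11 ± 0.57), Mir1931 (-5.00 ± 0.51) and Phgdh (-4.76 ± 0.75). The marginal zone genes Asb2 (1.35 ± 0.31) and Dtx1 and the immature B cell genes Lef1 (1.33 ± 0.24) and Myb (1.93 ± 0.44) were higher, with a marginal zone list median of 1.35 (camera adjusted p = 0.000174, and 0.504 with an estimated correlation). S1pr2 (1.70 ± 0.23), Edem1 (1.67 ± 0.35), Pik3ap1 (2.37 ± 0.20) and Tlr6 (1.12 ± 0.21) rose, and H2-Aa (-3.35 ± 0.46), Dock2 (-2.82 ± 0.69) and Notch1 (-0.58 ± 0.15) fell. The count was 316 without B6 FO replicate 1, 357 without NOD FO replicate 1 and 277 without NOD FO replicate 2.

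In the arrays labelled T2MZ, several genes of dividing cells were lower in NOD. Rrm2, which makes deoxynucleotides (-4.58 ± 0.73), Mki67 (-4.45 ± 0.86), the mitotic kinase Aurkb (-2.27 ± 0.47) and Cdk1 (-2.39 ± 0.61) fell, as did 5 of 20 cell cycle genes in all (11 adjusted over the list alone), with a median of -1.94 (camera adjusted p = 3.83e-08, and 0.318 with an estimated correlation). Of 9 marginal zone genes 1 passed, Asb2 (-2.01 ± 0.31), with a list median of -1.22 (camera adjusted p = 7.14e-06, and 0.203 with an estimated correlation). Of 9 follicular genes 1 passed, the inhibitory receptor Btla (0.58 ± 0.15), with a list median of 0.84 (camera adjusted p = 0.00140, and 0.0576 with an estimated correlation). A total of 720 genes passed, 427 higher and 293 lower, but 11 with only the arrays compared, 4 higher and 7 lower. The largest increases were Ctse (5.54 ± 0.41), Mtrex (5.52 ± 1.27), BC018473 (5.19 ± 0.27), the collagen gene Col6a4 (4.34 ± 0.31), the ubiquitin ligase Peli1 (4.19 ± 0.84), Zfp979 (4.12 ± 0.40), Scd2 (3.78 ± 0.30) and the apoptosis inhibitor Birc6 (3.75 ± 0.55). The largest decreases included Trim12a (-6.41 ± 0.27), Trim12c (-5.86 ± 0.37), Ifi213 (-5.70 ± 0.37), Rps9 (-5.41 ± 0.38), Phgdh (-5.36 ± 0.75), Hspa1a (-5.11 ± 0.97) and Slc15a2 (-5.09 ± 0.27). In the B cell receptor list Pik3ap1 (2.65 ± 0.20), Cd22 (1.96 ± 0.44) and the kinase Prkcb (2.13 ± 0.50) rose, with a median of 0.75 (camera adjusted p = 0.00140, and 0.318 with an estimated correlation). Interferon response genes fell in 3 cases, Rsad2 (-3.06 ± 0.46), Oas2 (-1.64 ± 0.42) and Ifih1 (-2.04 ± 0.53), and Stat2 rose (1.48 ± 0.26), with a list median of -1.38 (camera adjusted p = 3.11e-05, and 0.318 estimated). Ikbkb (2.72 ± 0.28), Ciita (2.77 ± 0.56), the Notch ligand Dll1 (1.17 ± 0.27) and Tlr6 (1.24 ± 0.21) were higher, and H2-Aa (-3.06 ± 0.46), Cd86 (-1.37 ± 0.25), Myb (-2.35 ± 0.44), Itgal (-1.13 ± 0.24) and Cd93 (-2.31 ± 0.28) lower. The count was 397 without B6 T2MZ replicate 1, 300 without NOD T2MZ replicate 1 and 321 without NOD T2MZ replicate 2.

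In the arrays labelled MZ, NOD and B6 differed in 721 genes, 453 higher and 268 lower in NOD. The sodium pump subunit Atp1b1 (4.90 ± 0.31), the actin-binding gene Rflnb (4.16 ± 0.34) and the gate transcript Fcer2a (2.50 ± 0.52) were higher in NOD, while Tlr3 (-1.81 ± 0.41), the Notch target Hes5 (-1.27 ± 0.34) and Myb (-2.25 ± 0.44) were lower. The follicular list had a median of 1.21, with no member past the threshold and 3 higher when adjusted over the list alone (camera adjusted p = 0.00146, and 0.0376 with an estimated correlation). Of 9 marginal zone genes 1 fell, with a median of -0.71 (camera adjusted p = 0.0457, and 0.566 with an estimated correlation). The other largest increases were BC018473 (5.41 ± 0.27), Ctse (5.08 ± 0.41), Scd2 (5.04 ± 0.30), Zfp979 (5.04 ± 0.40), AI506816 (4.38 ± 0.29) and Inpp5f (4.06 ± 0.32). The largest decreases included Trim12a (-6.92 ± 0.27), Trim12c (-5.49 ± 0.37), Rps9 (-5.39 ± 0.38), Slc15a2 (-5.05 ± 0.27), Ifi213 (-5.02 ± 0.37), the segregase Vcp (-4.93 ± 0.26) and the apolipoprotein Apoe (-4.59 ± 0.71). Of 13 class II MHC and costimulation genes 2 rose, Ciita (3.23 ± 0.56) and H2-Ob (0.69 ± 0.17), and 3 fell, including Cd86 (-1.78 ± 0.25) and H2-Aa (-2.87 ± 0.46), and the list did not pass (camera adjusted p = 0.0936). In the B cell receptor list Pik3ap1 (2.83 ± 0.20) and Cd22 (2.05 ± 0.44) rose, with a median of 0.62 (camera adjusted p = 0.00146, and 0.335 with an estimated correlation). Ikbkb (1.61 ± 0.28), Irak1 (1.93 ± 0.37), Stat2 (1.37 ± 0.26) and Dll1 (1.04 ± 0.27) were higher, and Rsad2 (-2.63 ± 0.46) and Dock2 (-3.17 ± 0.69) lower. All 12 myeloid genes were negative (median -0.65, camera adjusted p = 0.00491, and 0.566 with an estimated correlation), with a myeloid list median of 1.49 in B6 MZ replicate 2 and -0.14 in replicate 1. The count was 373 without B6 MZ replicate 2, 277 without NOD MZ replicate 1 and 275 without NOD MZ replicate 2.

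Marginal zone and follicular cells are the 2 mature outcomes of splenic B cell development. In B6, MZ cells had more S1pr3 (4.49 ± 0.61, SE, n = 2 and 2), which positions cells in the marginal zone, more Tlr3 (3.61 ± 0.41), more Cd1d1 (1.59 ± 0.27) and more of the Notch targets Asb2 (3.14 ± 0.31), Hes5 (1.94 ± 0.34), Dtx1 (1.89 ± 0.36) and Hes1 (1.55 ± 0.33) than FO cells. The costimulatory ligand Cd86 (1.48 ± 0.25) and the endotoxin co-receptor Ly96 (2.62 ± 0.37) were also higher. Fcer2a, a sort marker, was lower in MZ (-3.22 ± 0.52), as were Sox4 (-2.44 ± 0.45) and Btla (-0.92 ± 0.15). Of 9 marginal zone genes 6 rose (8 adjusted over the list alone) and none fell, with a list median of 2.76 (limma's camera, adjusted p = 2.13e-25, and 0.00106 with an estimated correlation). All 9 follicular genes were negative and 1 fell, with a median of -1.18 (camera adjusted p = 6.04e-07, and 0.00106 estimated). The Toll-like receptor list rose by a median of 0.24 (adjusted p = 0.000479, and adjusted p = 0.0203 with an estimated correlation, but 0.0639 estimated with the replicate number as a block), and the cell cycle list by 0.70 with no single member called (adjusted p = 1.25e-05, and 0.354 estimated). Myeloid genes were positive in 11 of 12 cases (median 0.39, camera adjusted p = 0.00857, and 0.458 with an estimated correlation), with a list median of 1.49 in B6 MZ replicate 2 and -0.14 in replicate 1. In all 156 genes passed, 111 higher and 45 lower in MZ. The spread behind these calls was shared with NOD, whose replicates differed less (0.28 against 0.514 in B6). The standard errors of contrasts within B6 may therefore be too small. With only the arrays compared 0 genes passed (limma, with 881 at an unadjusted p under 0.05). The largest increases included Tsga13 (4.74 ± 0.53), the muscle gene Nebl (4.45 ± 0.77), the G protein regulator Rgs10 (4.19 ± 0.41), the scavenging chemokine receptor Ackr2 (4.15 ± 0.50), the membrane repair gene Myof (3.96 ± 0.39), the fatty acid receptor Ffar2 (3.89 ± 0.48) and Oosp1 (3.75 ± 0.46). The largest decreases included the cytokine receptor Lifr (-3.57 ± 0.65), Atp1b1 (-3.24 ± 0.31), Crisp3 (-3.15 ± 0.53), Kctd14 (-3.12 ± 0.51), Zfp318 (-2.78 ± 0.48), Ssbp2 (-2.65 ± 0.49) and the phosphodiesterase Pde2a (-2.48 ± 0.30). With the replicate number as a block 235 genes passed, and with the class of 5' control signal as a block 913. The count was 68 without B6 FO replicate 1 and 79 without B6 FO replicate 2.

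The transitional pair gave fewer differences in B6. T2MZ cells had more Ffar2 (3.46 ± 0.48), Plbd1 (2.89 ± 0.48), Asb2 (1.89 ± 0.31) and Nbdy (1.58 ± 0.25) than T2FO cells, and less Sspn (-2.89 ± 0.42), the transporter Slco5a1 (-2.51 ± 0.30), Atp1b1 (-2.30 ± 0.31) and Lef1 (-1.37 ± 0.24). The sort markers Cr2 (1.40 ± 0.25) and Cd93 (-1.94 ± 0.28) differed as the sort makes them differ, which is no finding. In all 22 genes passed, 9 higher and 13 lower. The spread shared with NOD bears on these calls too, and with only the arrays compared 0 passed (limma, with 408 at an unadjusted p under 0.05). With the replicate number as a block 50 passed, 26 higher and 24 lower, and with the class of 5' control signal as a block 136 were higher and 113 lower. The marginal zone list had a median of 1.38 (camera adjusted p = 1.89e-10, and 0.0354 with an estimated correlation) and the immature B cell list a median of -0.53 (adjusted p = 7.93e-06, and 0.00530 estimated). Of 20 cell cycle genes 19 were positive and none passed alone, with a list median of 0.89 (adjusted p = 3.07e-11, and 0.207 estimated). All 9 T cell genes (median -0.34, camera adjusted p = 0.0071, and 0.244 with an estimated correlation) and all 6 NK cell genes (median -0.42, adjusted p = 0.0819) were negative, and B6 T2FO replicate 2 stood apart with list medians of 0.67 and 1.46. The count was 1 without B6 T2FO replicate 1, 10 without B6 T2FO replicate 2, 8 without B6 T2MZ replicate 2 and 0 without B6 T2MZ replicate 1 (limma, with 851 genes at an unadjusted p under 0.05).

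In NOD, macrophage transcripts were among the largest decreases in the arrays labelled MZ against those labelled FO. C1qc (-4.05 ± 0.52), Mrc1 (-4.02 ± 0.67), the scavenger receptor Cd163 (-3.89 ± 0.53), C1qa (-3.52 ± 0.54), Fcna (-3.44 ± 0.57), the lipase Lpl (-3.21 ± 0.47), Adamdec1 (-3.13 ± 0.49) and Treml4 (-3.13 ± 0.60) were the largest decreases. Of 12 myeloid genes 2 fell (7 adjusted over the list alone), with a median of -1.58 (camera adjusted p = 1.95e-19, and 0.022 with an estimated correlation). Ffar2 (3.13 ± 0.48), Ube2e2 (2.36 ± 0.23), AW011738 (1.81 ± 0.25), Asb2 (1.74 ± 0.31), Pxdc1 (1.12 ± 0.20) and Rab37 (1.04 ± 0.16) were the 6 genes called higher. Of 10 immature B cell genes 3 fell, Myb (-2.93 ± 0.44), Lef1 (-1.61 ± 0.24) and Sox4 (-2.83 ± 0.45), with a list median of -0.19 (camera adjusted p = 1.45e-09, and 0.000424 with an estimated correlation). The migration receptor S1pr2 (-1.59 ± 0.23) also fell. Of 9 marginal zone genes 8 were positive and 1 passed (5 rose and 1 fell adjusted over the list alone), with a median of 0.96 (camera adjusted p = 1.88e-08, and 0.0381 estimated). Altogether 44 genes passed, 6 higher and 38 lower, and 75 with the replicate number as a block. The count was 6 without NOD FO replicate 1, 21 without NOD FO replicate 2, 6 without NOD MZ replicate 1 and 7 without NOD MZ replicate 2.

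The NOD arrays labelled T2MZ and T2FO differed in 207 genes, 89 higher and 118 lower in those labelled T2MZ. With the 5' minus 3' control difference as a covariate the balance turned, with 293 higher and 241 lower. Rflnb (3.88 ± 0.34), Crisp3 (3.04 ± 0.53), Zfp318 (2.91 ± 0.48) and the carbonic anhydrase Car2 (2.59 ± 0.35) rose most, and Hspa1a (-5.25 ± 0.97), Eaf2 (-4.59 ± 0.39), Mgst1 (-4.11 ± 0.39) and 1810046K07Rik (-4.04 ± 0.52) fell most, leaving aside immunoglobulin variable genes, which were counted but not named. Of 12 plasma cell genes 5 fell (7 adjusted over the list alone), among them Tnfrsf17 (-2.23 ± 0.30), Creld2 (-1.57 ± 0.22), Edem1 (-2.35 ± 0.35) and Prdm1 (-2.90 ± 0.50), with a list median of -1.54 (camera adjusted p = 6.19e-15, and 0.00553 with an estimated correlation). The marginal zone list had a median of -0.82 with no member called (adjusted p = 5.06e-05, and 0.152 estimated), opposite in sign to the B6 contrast of the same labels. Myb (-3.68 ± 0.44), Sox4 (-2.11 ± 0.45) and Mki67 (-3.98 ± 0.86) were lower, and Numb (0.92 ± 0.18), Ccr6 (2.43 ± 0.41), Ikbkb (1.66 ± 0.28), Irak3 (1.66 ± 0.30) and the sort markers Cr2 (1.31 ± 0.25) and Fcer2a (2.44 ± 0.52) higher. The count was 406 without NOD T2FO replicate 1, 76 without NOD T2FO replicate 2, 89 without NOD T2MZ replicate 1 (46 higher and 43 lower) and 68 without NOD T2MZ replicate 2.

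Few genes were called in the MZ against FO contrast of both strains. The call was shared, with the same sign, by 3 genes higher and 2 lower, against 0.0366 and 0.094 for independent lists of those lengths, and 1 gene was called with opposite signs. Asb2, Ffar2 and Ube2e2 were higher in both, Sox4 and Slc15a3 were lower in both, and Eaf2 was higher in B6 and lower in NOD; these names were taken after the values were seen. Over all genes the contrasts of the strains had a correlation of 0.054, which is across genes, and genes are not independent replicates. With the replicate number as a block 7 genes were higher and 3 lower in both.

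Averaged over the strains, arrays labelled T1 had more S1pr3 (2.54 ± 0.43), Tsga13 (2.34 ± 0.38), the cytokine receptor Csf2rb (2.02 ± 0.36) and Lynx1 (1.93 ± 0.35) than arrays labelled FO. They had less Crisp3 (-3.39 ± 0.37), Apoe (-2.79 ± 0.50), Zfp318 (-2.77 ± 0.34) and the sort marker Fcer2a (-2.64 ± 0.37). Here the label problem of the NOD arrays bears on the direction, since Tlr3, which averaged 2.04 ± 0.29, was higher in T1 by 4.93 in NOD and lower in B6 (-0.84). Of 9 marginal zone genes 4 rose (7 adjusted over the list alone), with a list median of 1.35 (camera adjusted p = 1.15e-12, and 0.0108 with an estimated correlation). The NOD arrays carried most of this, with list medians of 2.40 and 2.42 in T1 against -0.01 and 0.97 in FO, while those of B6 were -0.39 and -0.47 against -0.69 and -0.45. Asb2 rose on average (1.98 ± 0.22), by 3.83 in NOD and 0.13 in B6. Notch1 (0.71 ± 0.10) and Ly96 (1.40 ± 0.26) rose, and the macrophage genes C1qc (-2.67 ± 0.37) and C1qa (-2.21 ± 0.38) fell. In all 181 genes passed, 110 higher and 71 lower, and 366 with the replicate number as a block. The B6 numbers of T1 and FO may be crossed or follow 5' signal (correlation across genes of -0.64), and with crossed numbers 626 passed. The count was 57 without B6 T1 replicate 1 (27 higher and 30 lower), 98 without B6 FO replicate 2, 85 without NOD T1 replicate 1, 68 without NOD T1 replicate 2 and 59 without NOD FO replicate 1. The NOD contrast alone gave 277 genes and the B6 contrast alone 262. The follicular list had a median of -0.69 (camera adjusted p = 4.62e-06, and 0.00545 with an estimated correlation).

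T3 and FO arrays differed in 8 genes over the strains, 4 higher and 4 lower in T3, and in 46 with the replicate number as a block. The B6 numbers of T3 and FO may be crossed or follow 5' signal (correlation across genes of -0.49), and with crossed numbers 168 passed. Cd93, a sort marker, was higher in T3 (1.68 ± 0.20), as were 1700097N02Rik (2.01 ± 0.25), Mgst2 (0.93 ± 0.15) and Slamf9 (0.90 ± 0.15). The immature B cell list had a median of 0.32 with no member called (camera adjusted p = 0.000101, and 0.0116 with an estimated correlation), and the interferon response list a median of 0.88 (adjusted p = 0.000135, and 0.365 estimated). The myeloid list, high in the NOD arrays labelled FO, had a median of -0.57 (camera adjusted p = 4.64e-06, and 0.324 with an estimated correlation). The count was 25 without B6 T3 replicate 1, 5 without B6 T3 replicate 2, 3 without B6 FO replicate 2, 1 without NOD T3 replicate 2 and 1 without NOD FO replicate 1.

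Whether the strain difference itself depended on lineage was tested as an interaction. Between MZ and FO labels 43 genes passed, 5 higher and 38 lower in the MZ comparison, and 89 with the replicate number as a block. Adamdec1 (-5.34 ± 0.69), Mrc1 (-5.02 ± 0.95), Cd163 (-4.63 ± 0.74), Mgst1 (-4.37 ± 0.55), Myb (-4.17 ± 0.62), C1qc (-3.89 ± 0.74) and S1pr2 (-1.97 ± 0.33) were lower, and Rflnb (2.88 ± 0.48), Atp1b1 (2.83 ± 0.43), Gimap3 (2.19 ± 0.36) and Pxdc1 (1.94 ± 0.29) higher. The myeloid list had a median of -2.24 (camera adjusted p = 3.78e-16, and 0.0302 with an estimated correlation), with array medians of 1.49 in B6 MZ replicate 2 against -0.14 in replicate 1, and of 2.01 and 1.37 in the NOD arrays labelled FO. The marginal zone list had a median of -1.53 (2.89e-12, and 0.02 estimated) and the follicular list 0.95 (7.28e-06, and 0.00637 estimated). The count was 7 without B6 FO replicate 1, 26 without B6 FO replicate 2, 100 without B6 MZ replicate 1, 28 without B6 MZ replicate 2, 28 without NOD FO replicate 1, 8 without NOD FO replicate 2, 8 without NOD MZ replicate 1 and 10 without NOD MZ replicate 2. Between T2MZ and T2FO labels 14 genes passed, 5 higher and 9 lower, and 55 with the replicate number as a block. Oosp1 (-4.64 ± 0.65), Rgs10 (-4.33 ± 0.58), Ackr2 (-4.11 ± 0.70) and Ptgr1 (-3.87 ± 0.65) were lower, and Rflnb (2.95 ± 0.48), Car2 (2.91 ± 0.50), Slco5a1 (2.57 ± 0.42) and Nab2 (1.62 ± 0.26) higher. All 9 marginal zone genes were negative, and 9 fell adjusted over the list alone against none over all genes, with a median of -2.09 (camera adjusted p = 8.83e-15, and 0.00981 estimated). None of the 14 calls was made (limma) without B6 T2FO replicate 1, B6 T2FO replicate 2, B6 T2MZ replicate 1, NOD T2FO replicate 2 or NOD T2MZ replicate 1, where 941, 1007, 1092, 619 and 884 genes had an unadjusted p under 0.05. The count was 2 without B6 T2MZ replicate 2, 26 without NOD T2FO replicate 1 and 2 without NOD T2MZ replicate 2.

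Finally, the genes that separated MZ from FO in B6 were followed in the other subsets as a signature of 100 genes higher and 45 genes lower in MZ. In the arrays labelled T1 the higher set had a median strain difference of 1.56, with 88 genes positive, and the lower set a median of -1, with 6 positive (camera adjusted p = 5.71e-47 and 3.39e-20, and 0.000507 and 0.000733 with an estimated correlation). In those labelled T2MZ the signs were opposite, with medians of -0.89 and 0.81 (adjusted p = 8.04e-34 and 9.30e-16, and 0.00201 and 0.00202 estimated). The medians were 0.13 and -0.29 in T2FO (adjusted p = 0.00233 and 0.000457, but 0.303 and 0.195 with an estimated correlation), and -0.30 and 0.14 in T3 (adjusted p = 4.81e-06 and 0.0872, and 0.242 and 0.42 estimated).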

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

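Every test of an explanation in this part was chosen only after the result was seen.

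The strain difference itself differed between MZ and FO labels in 43 genes, by a test of the interaction in limma with Benjamini-Hochberg adjustment. Macrophage transcripts were among them, with Adamdec1 at -5.34, Mrc1 at -5.02, Cd163 at -4.63 and C1qc at -3.89 on the log2 scale. Mgst1 (-4.37), Myb (-4.17) and S1pr2 (-1.97) also differed downwards, and Rflnb (2.88), Atp1b1 (2.83), Gimap3 (2.19) and Pxdc1 (1.94) upwards. Between T2MZ and T2FO labels the same test found 14 genes, among them Oosp1 (-4.64), Rgs10 (-4.33), Ackr2 (-4.11), Ptgr1 (-3.87), Rflnb (2.95), Car2 (2.91), Slco5a1 (2.57) and Nab2 (1.62). In T1 against FO all arrays of B6 moved one way and all of NOD the other in Tlr3 (mean 2.04, B6 -0.84, NOD 4.93), Lef1 (mean -0.79, B6 0.51, NOD -2.08) and Prf1 (mean 0.77, B6 -0.26, NOD 1.80), and this difference was not tested. Of 10092 probe sets without a single gene name, which entered no comparison of the report, 266 differed between the strains over the subsets (limma with Benjamini-Hochberg adjustment), 146 higher and 120 lower in NOD.

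The first pattern weighed is that subset markers of the NOD arrays did not follow their labels, which bears on every value above that uses a NOD subset. Correctly labelled subsets with a strain difference are argued against only as far as transcripts follow the proteins of the gates, by the values that raised the question, since Cr2 in T1 minus MZ was 0.37 ± 0.25 in NOD against -2.58 ± 0.25 in B6, and Cd93 was -0.36 ± 0.28 against 3.86 ± 0.28. MZ cells mixed into the T1 sort are argued against by the marginal zone list, which lay 1.02 higher in the NOD arrays labelled T1 than in those labelled MZ, where a mixture would lie lower. Labels attached to other subsets may account for it, since over 34 marker genes the labels as given ranked 256 of 720 assignments of the NOD arrays to B6 subset profiles (174 and 290 in single replicates). Both replicates gave the same best assignment, with a mean correlation across genes of 0.68 for their average against 0.082 for the labels. In it the NOD arrays labelled T1 went to B6 MZ, T2FO to T1, T3 to T2FO, FO to T3, T2MZ to FO and MZ to T2MZ. That moves each label 1 place back in the order of the deposited samples, with T1 moved to the end. Single placements are uncertain, because the B6 replicates against each other ranked their labels 20. They had 4 of 6 moved in the best assignment, T2FO exchanged with FO and T2MZ with MZ (0.45 against 0.35 for the labels). No value was recomputed under other labels, and a strain difference in which transcripts part from surface proteins stays open.

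The second pattern is the macrophage transcripts in the NOD arrays labelled FO. Macrophages in the sort may have brought them, since 8 of the 12 members of the myeloid list lay above all 10 other NOD arrays in both of these arrays, with Csf1r at 3.83 and 4.02 and C1qc at 4.24 and 3.92. Lyz2 (0.10 and 0.48, highest other NOD array 0.43), Itgam, S100a8 and S100a9 did not. The cells had been depleted through CD11b, and how many macrophages that left was not measured. A general rise of cells other than B cells is argued against. The T cell, NK cell, dendritic cell and erythroid lists had medians between -0.11 and 0.09 while the myeloid list rose by 1.68. The share of B cells itself was not tested, since macrophages in the sort would lower it too. The transcripts are not confined to these arrays, because B6 MZ replicate 2 had a myeloid list median of 1.49 against 2.01 and 1.37 here, and B6 arrays reached 3.96 in Csf1r, 2.94 in Lyz2 and 2.34 in Clec7a, though only 1.34 in C1qc. A biological difference between subsets stays open and untested.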

How the results depend on the processing

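Tests with the 5' covariate, the SD filter, array centring, the control class or crossed numbers as a block, 1 strain's contrast alone and pools crossed were chosen after seeing the data, and the others before. No filter as an alternative (now the same as the analysis itself), a stricter dim filter and cyclic loess were not run, because the deposited values are centred per probe set and hold no signal over background. Where an array is left out, the lone remaining array is assumed to vary like the other groups. Unless said otherwise, values are numbers of called genes and the cause was not tested.

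With only the arrays of the groups compared, which leaves few degrees of freedom, NOD against B6 gave 395 genes in T1, 14 in T2FO, 9 in T3, 21 in FO, 11 in T2MZ and 165 in MZ, and T1 against FO gave 34. The same setting gave 0 (limma, with the number at an unadjusted p under 0.05 in brackets) for MZ against FO in B6 (881), T2MZ against T2FO in B6 (408), T3 against FO (911) and the interactions of MZ with FO (928) and T2MZ with T2FO (680).

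With the difference of 5' and 3' control signal as a covariate NOD against B6 gave 4219 in T1, 2579 in T2FO, 1867 in T3, 1701 in FO, 2339 in T2MZ, 1614 in MZ and 5360 over subsets, where the 24 arrays were also taken as independent, which alone gave 3962 (2106 higher, 1856 lower). It gave 362 for MZ against FO and 86 for T2MZ against T2FO in B6, 76 and 534 for the same pairs in NOD, 499 for T1 against FO, 154 for T3 against FO, and 99 and 58 for the interactions of MZ with FO and T2MZ with T2FO. The balance of NOD against B6 turned with it against that fit over subsets (2329 higher, 3031 lower), in T1 (2007, 2212) and in T2FO (1024, 1555), and that of T2MZ against T2FO turned in B6 (51, 35) and in NOD (293, 241).

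With the mean of all probe sets of a gene NOD against B6 gave 385 in T2FO, 244 in T3, 436 in T2MZ, 464 in MZ and 433 over subsets, and T3 against FO gave 1. The balance turned with it in T2FO (175 higher, 210 lower) and over subsets (214, 219). With eBayes with trend and robust T2MZ against T2FO in B6 gave 0 (limma, 746 at an unadjusted p under 0.05), MZ against FO in NOD 16, T1 against FO 116, T3 against FO 1 and the interactions 18 and 2.

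With the replicate block NOD against B6 over subsets gave 275, which pairs unrelated pools of the strains by number. The same block gave for MZ against FO in B6 235, T2MZ against T2FO in B6 50, MZ against FO in NOD 75, T1 against FO 366, T3 against FO 46, the interactions 89 and 55, and the calls shared by the strains 10. With the pool as a random block T2MZ against T2FO in B6 gave 41, MZ against FO in NOD 68, T1 against FO 291, T3 against FO 28 and the interactions 72 and 50. Over subsets the 24 arrays gave 2655 with a random block and 3962 as independent, which counts arrays of 1 pool as replicates. Genes with an SD above the median gave 1622 over subsets, where fewer genes are tested, and crossing the FO and MZ numbers of B6 gave 49.

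With the B6 control class as a block MZ against FO in B6 gave 913, T2MZ against T2FO in B6 249, T1 against FO 579 and T3 against FO 140. With crossed numbers as a block T1 against FO gave 626 and T3 against FO 168. The NOD contrast alone gave 277 for T1 against FO and 24 for T3 against FO. The B6 contrast alone gave 262 for T1 against FO and 44 for T3 against FO. With arrays centred on their medians the interaction of T2MZ with T2FO gave 5.

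Leaving out 1 array or pool gave 685 to 1040 for NOD against B6 in T1, 291 to 881 in T2FO, 174 to 451 in T3, 277 to 487 in FO, 300 to 513 in T2MZ, 275 to 568 in MZ and 0 to 2401 over subsets (limma, 2574 at an unadjusted p under 0.05 where 0). It gave 68 to 112 for MZ against FO in B6, 0 to 10 for T2MZ against T2FO in B6 (limma, 851 at an unadjusted p under 0.05 where 0), 6 to 21 for MZ against FO in NOD, 68 to 406 for T2MZ against T2FO in NOD, 57 to 143 for T1 against FO, 1 to 25 for T3 against FO, and 7 to 100 and 0 to 26 for the interactions.

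The signature of B6 kept its direction but lost its call with an estimated correlation in T2FO (0.128 for the higher genes, -0.289 for the lower) and for the higher genes in T3 (-0.302). Reversed values were H2-Aa in NOD against B6 in T1 (0.06 with the mean of its probe sets), and, with the B6 contrast alone in T1 against FO, Tlr3 (-0.84), Cd1d1 (-0.30), Lef1 (0.51) and Prf1 (-0.26). The MHC class II list over subsets had the opposite direction with fry (adjusted p = 0.79).

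Of 94 list calls, 67 were lost and 27 held with an estimated correlation, 58 were lost with fry, 7 with arrays centred, and 1 with the replicate block. Of 723 values of named genes, 339 called, the replicate block took 14 below the threshold and lifted 28 past it, trend and robust took 72 below, and the mean of probe sets took 68 below and lifted 11. Only the arrays compared took 201 of 302 called values below. Crossing the FO and MZ numbers of B6 between the pools took 24 of 37 called over subsets below. Among the values followed with 1 array or pool left out, 1516 were called in the full fit. Leaving out 1 array gave 3556 values, of which 609 lost their call, 24 gained one and none changed sign while called.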

Other observations

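The lists of the next paragraph were written before the data were examined, and the tests of 5' signal, of probe variants and of other splits were chosen only after the result was seen.

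Beyond the genes named by the comparisons, some programmes moved as lists. Between T2MZ and T2FO labels the strain difference was lower in plasma cell genes, with a median of -1.70 and 8 of 12 lower adjusted over the list alone, against none over all genes (camera adjusted p = 5.06e-13, and adjusted p = 0.00981 with an estimated correlation). It was lower in cell cycle genes as well, with a median of -2.22 and none of 20 called over all genes (camera adjusted p = 8.83e-15, and 0.0834 with an estimated correlation). Between MZ and FO labels the cell cycle median was -1.22 (camera adjusted p = 4.34e-08, and 0.226 with an estimated correlation). In arrays labelled T1 against FO over the strains the interferon response list had a median of 0.67 (camera adjusted p = 1.39e-06, and 0.158 with an estimated correlation) and the immediate early and stress list a median of -1.52 (camera adjusted p = 9.73e-07, and 0.14 with an estimated correlation). A single array stood apart in the latter, NOD T1 replicate 2 at a list median of -3.04 against 0.29 in replicate 1. The Toll-like receptor list had a median of 0.29 in the same comparison with 2 of 16 called higher (camera adjusted p = 6.41e-06, and 0.00708 with an estimated correlation), and of these Tlr3 was lower in B6 (-0.84) and higher in NOD (4.93).

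Loss of 5' signal in B6 was tested as a source of the strain difference over the subsets. The NOD arrays labelled FO and MZ were set against the 2 B6 arrays whose 5' control signal was like that of NOD. There the 944 called genes kept a median of 0.889 of their difference over the subsets, with quartiles of 0.622 and 1.12. The sign was the same in 96.8%, which argues against that loss as the whole cause. All these arrays also enter the pool means, so the comparison is not independent, and the NOD arrays labelled FO carry the macrophage transcripts. The pool means do depend on how the arrays are joined, with 49 genes when the FO and MZ numbers of B6 are crossed between the pools.

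Strain variants under the probes were also tested, since the arrays were designed on the B6 sequence and a variant could lower a probe set in NOD. Of 328 genes called lower in NOD with further probe sets, 232 (70.7%) had other probe sets that differed by under 25% as much or the other way. Of 432 genes called higher, 332 (76.9%) did (Fisher's exact test, one-sided, p = 0.977). Each gene was represented by its most variable probe set, so its other probe sets differ less by selection, in both directions. These shares therefore say little about variants. Variants and expression cannot be told apart for genes called lower in NOD, because no probe sequences were used here and quiet probe sets of a gene also measure little.

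Other splits of the 8 arrays into 4 and 4 were fitted as the comparison itself was, with 1 mean per strain and side, which leaves 34 splits because the split by strain has no difference within strains. For T1 against FO 4 of the 34 splits, the real one included, called as many genes as the real split, which called 34, and the highest other split called 520, so chance is not excluded by this count. All 3 other splits keep the division of T1 from FO in NOD, so they hold part of the real difference. In the fit over all 24 arrays that division called 277 genes in NOD alone and 262 in B6 alone. The 24 splits that keep it in neither strain called at most 1. The split with 520 genes keeps it in NOD and puts B6 T1 replicate 1 with B6 FO replicate 2, the B6 arrays of this comparison with the higher 5' control signal, so the structure it points to is not of B6 alone. With crossed numbers as a block 626 genes were called. For T3 against FO the real split called 0 genes (limma, with 911 at an unadjusted p under 0.05), so that all 34 splits called as many by construction and the count says nothing about chance, and the highest other split called 27. The 181 and 8 genes of the report rest on the spread estimated over all 24 arrays. An earlier form of the test, with strain as an added term, was replaced because its outcome was fixed by the fit.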
